A study of Mus musculus with 36 samples.

How the data were processed

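RNA bound to ribosomes carrying phosphorylated ribosomal protein S6 (pS6) was sequenced from the olfactory epithelium of 8-week-old C57BL/6J wild-type male mice. Phosphorylation of S6 rises in neurons that have fired, so an antibody to pS6 enriches RNA from odor-activated cells. Mice were kept without odor for 4 h and then exposed for 90 min to 10 µL of odorant on filter paper, or to empty paper. Tissue was perfused before it was homogenized, per the labels. The 36 libraries form 12 groups of 3 mice in 3 sets of 12 libraries. Each set holds its own no-odor controls, a pair of components and their mixture: acetophenone and decanal (AD set), octanal and cis-3-hexenol (OC set), and a floral and a mint fragrance (FM set). The labels give the set as the batch, so comparisons inside a set were made within a batch.

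The deposited values are expected counts per gene, of which 11.1% to 16.4% per library were fractional. They were rounded for the tests. The labels name STAR 2.7.10b, Salmon 1.10.1, R 4.4.2 and the build GRCm39, but not the gene annotation or which step gave the counts. Expected counts share a read that fits several genes between them, so closely similar receptors are not fully separate measurements. Of 57010 gene identifiers, 52029 were named from a GENCODE vM21 annotation of GRCm38. The 4981 others held 0.284% to 0.650% of the counts of a library. Symbols are those of that annotation, and positions are not given because the builds differ. A check for duplicated libraries found none.

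Library totals ran from 16.04 to 26.4 M counts, of which 37701 to 160196 fell on the 1107 listed olfactory receptor genes. The method was tested on simulated data with the control means, the library sizes and the gene-wise spread of each set, with genes changed up or down. At an 8-fold change 71.1%, 85.1% and 94.0% of changed receptor genes were recovered in the AD, OC and FM sets. At a 4-fold change the shares were 41.7%, 37.0% and 70.8%, and at a 2-fold change 8.16%, 6.25% and 28.3%. For the interaction test and an 8-fold change they were 47.9%, 56.2% and 64.0%. Between 3 and 8 unchanged genes were called in these receptor and all-gene runs.

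Computation used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each set was fitted alone with the 4 groups as terms. Genes were kept by filterByExpr (minimum count 10, minimum total 15) and libraries were scaled by TMM. Tests were the 2-sided quasi-likelihood tests of edgeR (glmQLFit, glmQLFTest; prior count 0.125). P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 changes were computed from the change and its F statistic. Counts scaled to a library of 1 M (CPM) used TMM-scaled library sizes and are given as mean ± SD, n = 3. Each odor was compared with the controls of its set, each mixture with each component, and each mixture with the sum of the log2 changes of its components (the interaction). Octanal and decanal were compared in a joint fit of 24 libraries and 8 groups, each odor against its own controls. That comparison crosses batches. The share of counts on receptor genes was compared by an exact permutation test, 2-sided.

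Gene lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, for lists with at least 3 tested members. The 25 lists, the comparisons, the rule for naming genes and the alternatives were fixed before the data were examined. The exception is the class I receptor list, whose planned name pattern matched no gene and was replaced. A further 2 lists, class II receptors and receptor pseudogenes, were added later. Class I receptors were taken as MOR families up to 42, which gave a class to 1093 receptors. Near-identical receptor copies were found with blastn 2.17.0 among 3229 receptor transcripts as at least 95% identity over at least 200 bases, and 410 receptors had at least 1 copy.

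Mixtures and components share control libraries, which alone makes their log2 changes correlate. To size this effect, 20 tables with unchanged groups were simulated per set. The place of a mixture between its components was measured as a slope over genes. Its departure from the midpoint of the component profiles was regressed on the difference between those profiles. Both were first centred on their medians over the genes used. The scale is 0.5 at the first component and -0.5 at the second. Component libraries were placed with themselves left out of the scale.

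The genes named were, for each odor, the 8 receptor genes called higher and the 4 called lower with the smallest p, and 4 other genes each way, among genes whose libraries did not overlap between groups. Chance gives that 10% of the time for 3 against 3. Predicted genes and pseudogenes were left out. For mixture against component, interaction and octanal against decanal, 5 receptor genes each way were named. For lists, up to 4 called members were eligible. Receptors listed beforehand as acetophenone or octanal responders were named in every comparison of that odor. Genes chosen after their values were seen are identified as such. A gene that the rule selects is not reported here.

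The alternatives were DESeq2, relative log expression size factors, TMM without receptor genes, no filter on low counts, adjustment over the receptor list alone, all 36 libraries in a single fit, only the 6 libraries compared, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were a scaling to the median receptor gene, removal of the genes of 4 lists (mitochondrial, ribosomal protein, erythroid and immune), and a closer look at leaving out octanal replicate 2 and acetophenone replicate 1. Libraries made before immunoprecipitation were not analysed here, so enrichment over total RNA was not computed.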

Results

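The pS6 immunoprecipitation RNA-seq libraries numbered 36, with 3 mice in each of 12 groups. They came from olfactory epithelium after exposure to single odorants, binary mixtures, complex fragrances or no odor. In the AD set, libraries held 21.8 to 23.7 M counts in controls, 23.5 to 23.6 with acetophenone, 19.7 to 20.4 with decanal and 21.5 to 21.8 with the mixture. Libraries of the OC set held 16.04 to 19.2 M in controls, 18.6 to 21.5 with octanal, 17.0 to 21.2 with cis-3-hexenol and 21.6 to 24.5 with the mixture. Those of the FM set held 23.3 to 26.4 M in controls, 26.1 to 26.2 with the floral fragrance, 17.9 to 26.04 with the mint fragrance and 25.9 to 26.1 with the floral-mint fragrance.

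Olfactory receptor genes took a small share of every library, from 0.225% to 0.706% of its counts. In controls the share was 0.366% ± 0.0259 (SD, n = 3) in the AD set, 0.243% ± 0.0229 in the OC set and 0.327% ± 0.0211 in the FM set. It was 0.542% ± 0.0490 with acetophenone, 0.453% ± 0.0174 with decanal and 0.448% ± 0.0333 with their mixture. It was 0.599% ± 0.113 with octanal, 0.447% ± 0.0283 with cis-3-hexenol and 0.631% ± 0.0317 with the mixture of these. With the fragrances it was 0.429% ± 0.0333 for floral, 0.484% ± 0.0505 for mint and 0.466% ± 0.0490 for floral-mint. The ratio to control ran from 1.22 for the acetophenone-decanal mixture to 2.6 for the octanal-hexenol mixture. All 3 libraries of each odor group lay above all 3 controls of their set. The exact permutation p was 0.1 in each of the 9 comparisons, which is the smallest that 3 against 3 allows.

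**Figure D1:**
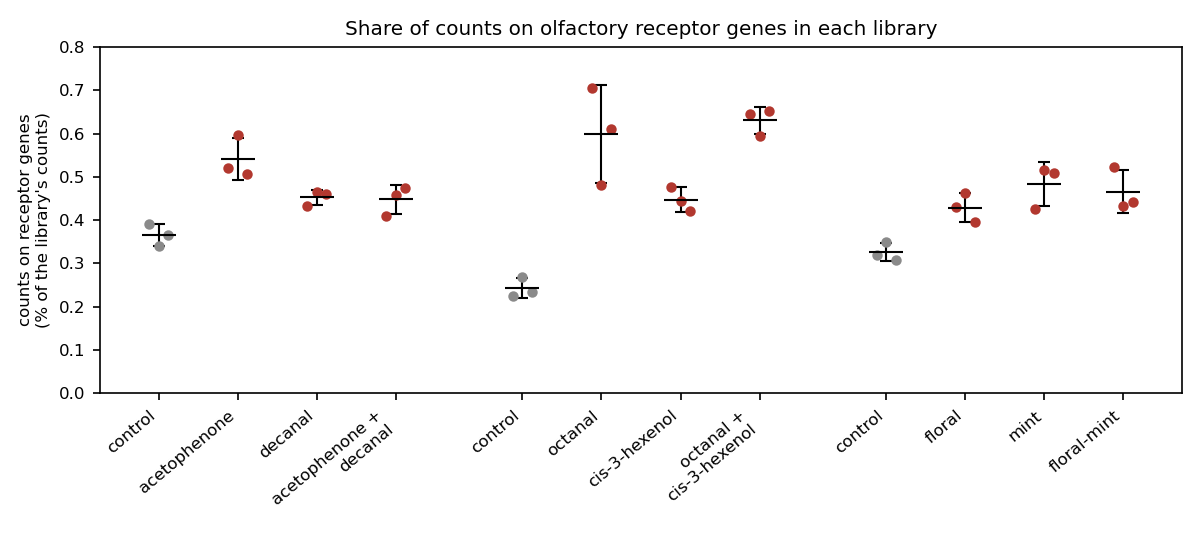
Share of library counts on olfactory receptor genes (y axis, percent) for each library (points) with the mean and SD of each group of 3. Odor groups average 0.429% to 0.631% and controls 0.243% to 0.366%.

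Each odor was compared with the no-odor controls of its set to find the receptor genes whose RNA was more abundant on pS6-bearing ribosomes after exposure. In the AD set 868 receptor genes were among 19514 tested. Acetophenone gave 118 called receptor genes, 110 higher and 8 lower (141 adjusted over the list alone). The smallest p belonged to Olfr736 (ENSMUSG00000047716), at 1.46 ± 0.12 CPM in controls and 61.5 ± 7.26 with acetophenone, a log2 change of 5.40 (SE 0.250, adjusted p 8.49e-08). The next receptor genes were Olfr913, Olfr1026, Olfr491, Olfr1126, Olfr143, Olfr1104 and Olfr1283, with log2 changes of 3.55 to 5.29 and adjusted p of 6.14e-07 to 1.89e-05. Lower receptor genes were Olfr1391, Olfr716, Olfr723 and Olfr1341, at -1.13, -1.38, -1.62 and -0.93 (adjusted p 0.00305 to 0.0193). Among all genes 823 were higher and 248 lower, and 145 and 146 with scaling to the median receptor gene. Of genes other than receptors, Gnal, Spef2, Heg1 and Vwa3a were higher by 1.17, 1.17, 1.53 and 1.02, and Ctsk, Jdp2, Acp5 and Fabp4 were lower at -1.58, -0.82, -1.73 and -3.40. The count over all genes, 1071, was 396 without control replicate 2, 453 without control replicate 3 and 386 without acetophenone replicate 2.

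Decanal gave 124 called receptor genes, 66 higher and 58 lower (109 adjusted over the list alone). By DESeq2, with all 36 libraries in a single fit or without a filter on low counts, more were lower than higher. Olfr332 (ENSMUSG00000050813) had 6.30 ± 0.815 CPM in controls and 229 ± 16.9 with decanal, a log2 change of 5.18 (SE 0.143, adjusted p 6.68e-11). Olfr55, Olfr1383, Olfr509, Olfr716, Olfr1419, Olfr1426 and Olfr1254 followed, with log2 changes of 3.96 to 5.04 and adjusted p of 8.8e-10 to 1.77e-07. Lower receptor genes were Olfr711, Olfr1391, Olfr1341 and Olfr59, at -1.78, -1.48, -1.58 and -1.95. The mixture gave 171 called receptor genes, 115 higher and 56 lower (169 adjusted over the list alone). Olfr332 again had the smallest p, with 125 ± 13.6 CPM and a log2 change of 4.31 (SE 0.138, adjusted p 5.31e-10). Olfr55, Olfr1383, Olfr1419, Olfr716, Olfr509, Olfr1026 and Olfr1426 followed, at 2.98 to 4.65. Lower in the mixture were Olfr711, Olfr169, Olfr59 and Olfr1229, at -1.48, -1.41, -1.72 and -1.17. Over all genes decanal gave 2102 higher and 2252 lower, and the mixture 2136 higher and 2032 lower. Under scaling to the median receptor gene the decanal count was 2210, with more higher than lower, and the mixture count 1896, with 1195 higher and 701 lower. The decanal count of 4354 was 2879 without decanal replicate 1, and the mixture count of 4168 was 2695 without control replicate 2. Rasl11a, Cartpt and Med21 were higher in both, by 1.86, 1.94 and 1.17 with decanal and by 1.43, 1.96 and 1.196 with the mixture. Selenot was higher with decanal by 1.27 and Fam213b with the mixture by 1.48. Copb1, Jup and Ncbp1 were lower in both, at -1.204, -1.13 and -0.88 with decanal and -1.07, -0.98 and -0.76 with the mixture.

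For the OC set 859 receptor genes were among 19568 tested. Octanal gave 208 called receptor genes, 184 higher and 24 lower (199 adjusted over the list alone). Olfr332 had 7.11 ± 1.18 CPM in controls and 159 ± 26.2 with octanal, a log2 change of 4.48 (SE 0.183, adjusted p 7.63e-10). Olfr1368, Olfr716, Olfr1383, Olfr695, Olfr370, Olfr287 and Olfr479 followed, at 3.12 to 5.08 with adjusted p of 1.16e-09 to 7.74e-08. Olfr728, Olfr1264, Olfr358 and Olfr934 were lower, at -0.80, -0.74, -0.86 and -2.69. The mixture of octanal and cis-3-hexenol gave 205, of which 198 were higher and 7 lower (197 adjusted over the list alone). Olfr332 had 157 ± 8.45 CPM, a log2 change of 4.47 (SE 0.183, adjusted p 7.87e-10), followed by Olfr1368, Olfr1383, Olfr716, Olfr695, Olfr479, Olfr370 and Olfr1380 at 3.20 to 5.56. Lower were Olfr728, Olfr539, Olfr166 and Olfr460, at -0.72, -1.12, -0.56 and -1.65. With scaling to the median receptor gene the mixture split was 165 higher and 58 lower.

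Cis-3-hexenol gave 68 called receptor genes, all higher (86 adjusted over the list alone). The count of lower receptor genes was 0 in edgeR, with 7 lower at an unadjusted p under 0.05, 2 lower adjusted over the list alone, 3 lower by DESeq2 and 24 lower with scaling to the median receptor gene. The count of 68 was 45 without cis-3-hexenol replicate 1. Olfr1215 (ENSMUSG00000100016) had 0.660 ± 0.165 CPM in controls and 14.5 ± 5.11 with cis-3-hexenol, a log2 change of 4.45 (SE 0.322, adjusted p 4.33e-06). Olfr398, Olfr124, Olfr1240, Olfr1226, Olfr476, Olfr342 and Olfr1243 followed, at 2.78 to 4.57 with adjusted p of 4.33e-06 to 4.04e-05.

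Over all genes in the OC set, 3509 were higher and 2812 lower with octanal, 504 and 619 with cis-3-hexenol, and 3457 and 2900 with the mixture. With scaling to the median receptor gene these splits were 1703 and 3321, 103 and 4578, and 909 and 6744. The octanal count of 6321 was 3932 without octanal replicate 1. The cis-3-hexenol count of 1123 was 500, 566 and 360 without control replicates 1, 2 and 3, and 533, 271 and 373 without cis-3-hexenol replicates 1, 2 and 3. It was 1997 by DESeq2 and 2180 with only the 6 libraries compared. With all 36 libraries in a single fit it was 3182, with 1824 higher and 1358 lower. Heg1 was higher by 2.47, 1.42 and 2.55 with octanal, cis-3-hexenol and the mixture, and Kcng1 by 4.14, 2.698 and 4.22. Vsnl1 was higher by 1.98 with octanal and 1.88 with the mixture, Scg3 by 2.01 with octanal and Gadl1 by 2.07 with the mixture. With cis-3-hexenol Lrrc3b and Ss18l1 were higher by 1.95 and 1.34. Tent5c, Pdzk1ip1 and Rhd were lower in all 3 comparisons, at -1.74, -1.84 and -3.17 with octanal, -1.18, -1.26 and -2.02 with cis-3-hexenol, and -1.58, -1.81 and -2.54 with the mixture. Itgb3 was lower with octanal at -2.57, Tspo with cis-3-hexenol at -1.27 and Ermap with the mixture at -3.06. Rhd and Ermap are genes of red blood cells.

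In the FM set 847 receptor genes were among 19204 tested. The floral fragrance gave 97 called, 82 higher and 15 lower (95 adjusted over the list alone). With all 36 libraries in a single fit floral gave 60, 59 higher and 1 lower. The mint fragrance gave 121, 108 higher and 13 lower (130 adjusted over the list alone and 76 with all 36 libraries in a single fit). The floral-mint fragrance gave 113, 101 higher and 12 lower (120 adjusted over the list alone). Olfr48 (ENSMUSG00000075072) had 6.67 ± 1.18 CPM in controls, 142 ± 11.3 with floral, 143 ± 7.56 with mint and 116 ± 13.0 with floral-mint. Its log2 changes were 4.41 (SE 0.133, adjusted p 5.15e-11), 4.42 (SE 0.134, adjusted p 3.96e-11) and 4.12 (SE 0.132, adjusted p 1.2e-10). With floral it was followed by Olfr167, Olfr1260, Olfr169, Olfr171, Olfr1284, Olfr473 and Olfr46, at 2.79 to 4.29. With mint, Olfr183 (ENSMUSG00000062105) had 215 ± 41.5 CPM against 8.67 ± 0.509, a log2 change of 4.63 (SE 0.145, adjusted p 3.96e-11). It was followed by Olfr1260, Olfr169, Olfr181, Olfr187, Olfr1123 and Olfr191, at 3.21 to 4.53. With floral-mint Olfr183, Olfr1260, Olfr167, Olfr169, Olfr1123, Olfr181 and Olfr171 followed Olfr48, at 2.48 to 4.28. Olfr536 was lower in all 3 comparisons, at -0.46, -0.60 and -0.47. Also lower were Olfr1232, Olfr506 and Olfr523 with floral at -1.07, -1.81 and -0.81, Olfr777, Olfr1228 and Olfr694 with mint at -0.96, -0.57 and -1.25, and Olfr1232, Olfr31 and Olfr726 with floral-mint at -0.89, -0.66 and -0.42.

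Over all genes in the FM set, 1671 were higher and 1027 lower with floral, 1364 and 781 with mint, and 1232 and 619 with floral-mint. Scaling to the median receptor gene turned the floral-mint split to 408 and 557. With all 36 libraries in a single fit the splits were 643 and 138 with floral, 563 and 119 with mint, and 523 and 130 with floral-mint. The floral count of 2698 was 967 without control replicate 1, 1672 without control replicate 3 and 1186 without floral replicate 3. The mint count of 2145 was 982 and 1083 without control replicates 1 and 3, and 1033 and 3336 without mint replicates 2 and 3. The floral-mint count of 1851 was 839 and 904 without control replicates 1 and 3, and 1189, 1153 and 1018 without floral-mint replicates 1, 2 and 3. Heg1, Omp and Dusp14 were higher in all 3 comparisons, by 1.47, 0.73 and 1.18 with floral, 1.68, 0.79 and 1.31 with mint, and 1.53, 0.72 and 1.28 with floral-mint. Gng13 was higher by 1.35 with floral and 1.48 with floral-mint, and Nptx2 by 1.51 with mint. Lower with floral were Gne, Anxa6, Kyat3 and Hsd17b6, at -0.67, -0.60, -0.68 and -0.55. Lower with mint were Tpm4, Mmp14, Mmp13 and Spp1, at -0.69, -0.60, -1.23 and -0.94. Lower with floral-mint were Car3, Mmp14, Tubb6 and Cnn2, at -1.11, -0.62, -0.81 and -0.72.

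**Figure D2:**
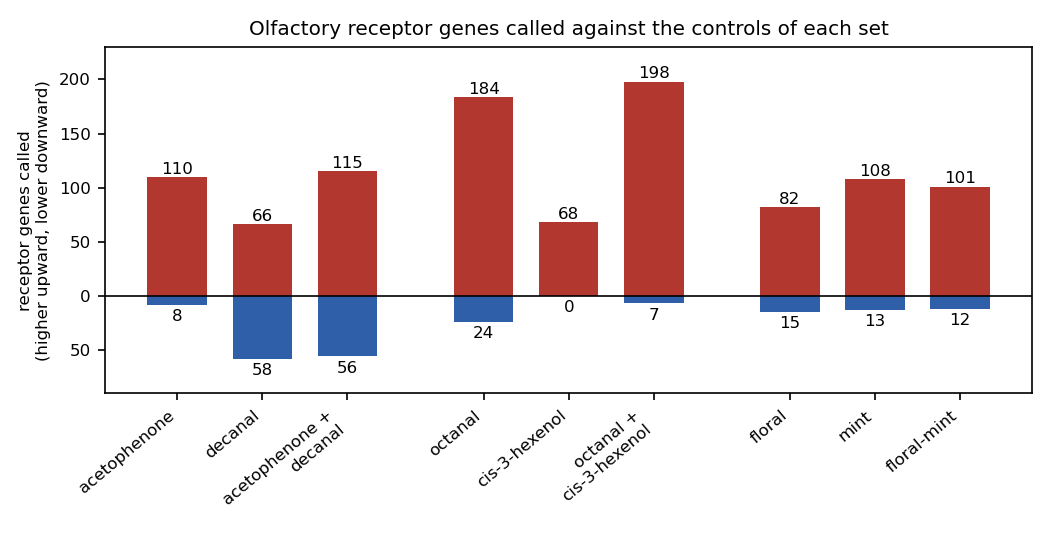
Number of olfactory receptor genes called higher (upward bars) and lower (downward bars) than control for each of the 9 odor groups. Counts of higher genes run from 66 with decanal to 198 with the octanal-hexenol mixture.

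Some receptors had been listed beforehand as responders. Of the 5 listed for acetophenone, Olfr151 was not among the genes tested. The other 4, Olfr983, Olfr145, Olfr923 and Olfr160, were higher with acetophenone by 4.46, 4.57, 4.72 and 4.44 (SE 0.401 to 0.489, adjusted p 4.1e-05 to 0.000104). In the acetophenone-decanal mixture they were higher by 3.95, 3.76, 4.49 and 3.75 (adjusted p 4.39e-05 to 0.000149). Olfr160 has a near-identical copy, Olfr151, with which it can share reads. For octanal the listed receptor was Olfr2, which rose from 4.17 ± 2.44 to 29.98 ± 11.96 CPM, a log2 change of 2.82 (SE 0.356, adjusted p 3.9e-05), and was higher in the mixture by 2.52. Other named receptors with a near-identical copy include Olfr55, Olfr1383, Olfr509, Olfr1426, Olfr59, Olfr169, Olfr171, Olfr287, Olfr1380, Olfr476, Olfr1283 and Olfr1284.

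Whether a mixture raises the receptor genes that its components raise was examined by overlap. In the AD set 171 receptor genes were higher with acetophenone or decanal, and 112 of them (65.5%) were also higher with the mixture. In the OC set the numbers were 213 and 184 (86.4%), and in the FM set 143 and 97 (67.8%). Receptor genes higher with the mixture and neither component numbered 3, 14 and 4. Those of the AD set, chosen after values were seen, were Olfr394, Olfr746 and Olfr1358 at 2.03, 2.36 and 1.79. Those of the FM set, chosen likewise, were Olfr744, Olfr63, Olfr59 and Olfr1392 at 1.69, 1.11, 0.80 and 0.86. The number of receptor genes higher with the mixture and above both components by test was 0 in each set in edgeR. At an unadjusted p under 0.05 the numbers were 0, 3 and 3, and by DESeq2 0 in each set. The 3 in the OC set, chosen after values were seen, were Olfr479, Olfr322 and Olfr1383, and the 3 in the FM set were Olfr744, Olfr63 and Olfr145.

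Acetophenone and decanal shared 5 higher receptor genes, against 8.36 expected from independent sets. These, chosen after values were seen, were Olfr1384, Olfr123, Olfr1126, Olfr1085 and Olfr1283. Octanal and cis-3-hexenol shared 39, against 14.6, and floral and mint 47, against 10.5. The mixture shared 73 with acetophenone (expected 14.6) and 42 with decanal (8.74). In the OC set it shared 165 with octanal (42.4) and 58 with cis-3-hexenol (15.7), and in the FM set 71 with floral (9.78) and 72 with mint (12.9). Unchanged groups simulated against shared controls gave 0 shared receptor genes in every case. Tables without any change yield few calls, so this does not exclude an effect of the shared controls on the overlaps. The expected numbers also take every receptor gene as equally likely to be called, which was not tested. Part of any excess in correlation may still come from the shared controls. Across receptor genes, which are not independent replicates, log2 changes of the components correlated at r 0.0786, 0.346 and 0.507 in the AD, OC and FM sets, against means of 0.516, 0.511 and 0.477 in simulation. Their covariances were 0.153, 0.454 and 0.516, against 0.194, 0.138 and 0.0823. Covariances with the mixture were 1.44 for acetophenone, 1.03 for decanal, 1.85 for octanal, 0.676 for cis-3-hexenol, 0.715 for floral and 0.792 for mint, against simulated means of 0.0827 to 0.189. The correlations with the mixture were 0.636, 0.549, 0.878, 0.563, 0.763 and 0.750 in the same order. For decanal and cis-3-hexenol these lay under the highest of the simulated values, 0.555 and 0.570.

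Mixture and component were then compared directly. The components of the AD and OC mixtures shared the volume that a single odorant filled. A lower value with these mixtures can therefore not be told apart from a smaller amount of the component. The AD mixture differed from acetophenone in 156 receptor genes, 48 higher and 108 lower (136 adjusted over the list alone), and from decanal in 53, 47 higher and 6 lower (110 adjusted over the list alone). Over all genes these counts were 5013 and 56. Of the 110 receptor genes higher with acetophenone, 50 were lower with the mixture than with acetophenone, and of the 66 higher with decanal, 5 were lower than with decanal. The median log2 change of the acetophenone receptors was 3.44 with acetophenone and 2.01 with the mixture, and that of the decanal receptors was 2.43 with decanal and 2.00 with the mixture. Above acetophenone were Olfr332, Olfr55, Olfr716, Olfr1383 and Olfr1419, by 3.96 to 5.21, and below it Olfr736, Olfr531, Olfr1463, Olfr30 and Olfr43, at -2.04, -2.20, -2.89, -1.87 and -1.77. Above decanal were Olfr736, Olfr1026, Olfr895, Olfr1104 and Olfr1047, by 3.61 to 5.51, and below it Olfr509, Olfr332, Olfr789, Olfr55 and Olfr17, at -1.198, -0.87, -1.51, -0.98 and -1.52.

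The OC mixture differed from octanal in 11 receptor genes, all higher (22 adjusted over the list alone). The count of lower ones was 0 in edgeR, with 39 at an unadjusted p under 0.05, and 1 by DESeq2. The count of 11 was 7 without octanal replicate 2 and 7 without mixture replicate 1. Olfr1215, Olfr1226, Olfr467, Olfr1225 and Olfr281 were higher by 2.13 to 4.27. From cis-3-hexenol the mixture differed in 131, 116 higher and 15 lower (134 adjusted over the list alone), and the count was 83 without cis-3-hexenol replicate 2. Higher were Olfr332, Olfr1383, Olfr1368, Olfr479 and Olfr370, by 3.34 to 5.82, and lower Olfr728, Olfr1416, Olfr1264, Olfr1294 and Olfr1297, at -1.197, -1.76, -0.84, -1.31 and -0.97. Over all genes the counts were 14 against octanal and 2523 against cis-3-hexenol. Of receptor genes higher with octanal none were lower with the mixture than with octanal, and of those higher with cis-3-hexenol 4 were lower. The median log2 change of the octanal receptors was 2.78 with octanal and 2.73 with the mixture, and that of the cis-3-hexenol receptors 2.22 and 2.72.

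The floral-mint fragrance differed from floral in 18 receptor genes, all higher (30 adjusted over the list alone). The count of lower ones was 0 in edgeR, with 43 at an unadjusted p under 0.05, and 4 by DESeq2. Olfr183, Olfr181, Olfr191, Olfr187 and Olfr357 were higher by 2.66 to 3.79. From mint it differed in 18, 11 higher and 7 lower (58 adjusted over the list alone, 45 by DESeq2 and 78 without a filter on low counts). The larger direction turned in some of the alternatives. Olfr167, Olfr874, Olfr46, Olfr876 and Olfr145 were higher by 2.50 to 4.78, and Olfr281, Olfr506, Olfr1087, Olfr187 and Olfr1047 lower at -1.93, -1.61, -2.81, -1.15 and -1.87. Over all genes the counts were 23 and 20. The median log2 change of the floral receptors was 2.16 with floral and 2.12 with floral-mint, and that of the mint receptors 2.37 with mint and 1.91 with floral-mint.

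The interaction test compared each mixture with the sum of the log2 changes of its components. In the AD and OC sets the smaller amount of each component in the mixture enters this test as well. Over all genes it called 47 in the AD set (40 below the sum) and 17 in the OC set (9 below). It called 7 receptor genes in the AD set, 1 above and 6 below the sum (10 adjusted over the list alone, 27 by DESeq2, 28 without a filter on low counts and 0 with the replicate number as a block). Olfr1391 was above by 1.54, and Olfr1283, Olfr1126, Olfr509, Olfr789 and Olfr123 were below, at -3.05, -2.79, -1.51, -1.78 and -1.73 (adjusted p 0.0142 to 0.0366). This count was 4, 1 and 0 without control replicates 1, 2 and 3, 3 without acetophenone replicate 2, 3, 0 and 1 without decanal replicates 1, 2 and 3, and 4, 2 and 4 without mixture replicates 1, 2 and 3. In the OC set 7 receptor genes were below the sum (25 adjusted over the list alone, 33 by DESeq2, 28 with all 36 libraries in a single fit and 59 without a filter on low counts). The count above the sum was 0 in edgeR, with 3 at an unadjusted p under 0.05, and 0 by DESeq2. Olfr124, Olfr398, Olfr476, Olfr1243 and Olfr1463 were at -2.84, -2.84, -3.40, -3.78 and -2.71. The OC count was 4 without control replicate 1, control replicate 3, octanal replicate 1, mixture replicate 1 or mixture replicate 2, 24 without octanal replicate 2 and 18 without octanal replicate 3.

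Over all genes 695 departed from the sum in the FM set (3.619% of those tested), 199 above and 496 below. Of receptor genes 49 departed (5.785%), 2 above and 47 below (53 adjusted over the list alone, 25 with all 36 libraries in a single fit and 91 without a filter on low counts). Of these 47 receptor genes, 37 were higher with both fragrances. Olfr48 was below by the smallest p, at -4.71 (SE 0.172, adjusted p 7.54e-10), followed by Olfr169, Olfr1260, Olfr1284 and Olfr473 at -3.64, -3.36, -4.30 and -4.04. Olfr1020 and Olfr536 were above, by 2.696 and 0.60. The count was 32 without floral replicate 2, 31 without mint replicate 2 and 30 without floral-mint replicate 3. Over the 47 receptor genes higher with both fragrances, the median log2 change was 2.09 for the lower component, 2.82 for the higher component, 2.85 for floral-mint and 5.13 for the sum. Floral-mint lay between the components in 33 of them, above both in 6 and below both in 8. Over the 39 receptor genes higher with octanal and with cis-3-hexenol the medians were 2.07, 3.27, 3.04 and 5.25. For the 5 higher with acetophenone and with decanal they were 1.97, 3.10, 1.83 and 5.07, and the mixture lay below both components in 2 of the 5.

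The place of each mixture between its components was measured over the receptor genes that differed between the components, 268, 241 and 60 in the AD, OC and FM sets. The mixture libraries averaged -0.0191 ± 0.0346 (SD, n = 3) in the AD set, 0.163 ± 0.0367 in the OC set, on the side of octanal, and 0.0689 ± 0.0130 in the FM set. Over all receptor genes tested the averages were 0.0111 ± 0.0445, 0.199 ± 0.0345 and 0.0387 ± 0.0106. With each component library in turn left out of this scale, they ran from -0.0229 to 0.0301 in the AD set (without acetophenone replicate 3 and decanal replicate 3) and from 0.136 to 0.218 in the OC set (without octanal replicate 3 and cis-3-hexenol replicate 1). For floral-mint the average was -0.000584 and -0.0054 without floral replicates 1 and 2, and 0.0815 and 0.0612 without mint replicates 1 and 3. On the scale of differing receptor genes, left-out component libraries averaged 0.471 for acetophenone, -0.465 for decanal, 0.453 for octanal, -0.461 for cis-3-hexenol, 0.488 for floral and -0.484 for mint. Those genes were chosen with the left-out libraries included, which favors such values. Across all receptor genes tested the averages were 0.417, -0.414, 0.385, -0.431, 0.343 and -0.354 in the same order. Over genes other than receptors the AD mixture averaged -0.282 ± 0.0425, near left-out decanal at -0.256 ± 0.0452, and left-out acetophenone averaged 0.247. The OC mixture averaged 0.231 ± 0.105, near left-out octanal at 0.227, and left-out cis-3-hexenol averaged -0.348. In the FM set this scale did not separate the components, at 0.0248 for left-out floral and 0.141 for left-out mint.

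**Figure D3:**
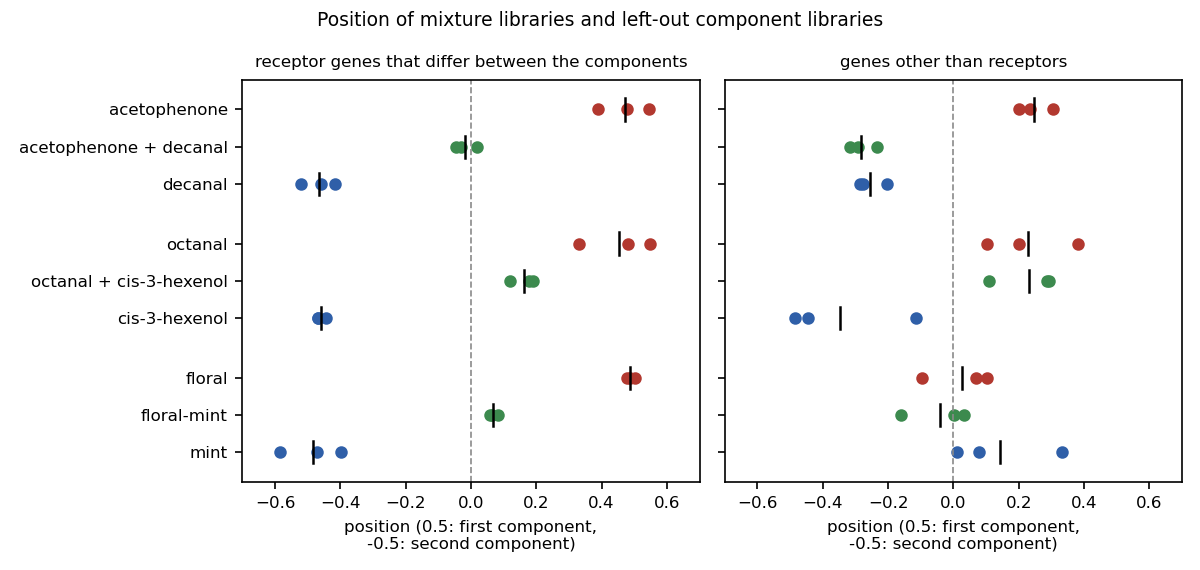
Position of each library (points, black bars are group means) between the components of its set, with 0.5 at the first and -0.5 at the second component, for receptor genes that differ between components and for genes other than receptors. Over receptor genes the mixtures average -0.0191, 0.163 and 0.0689 in the AD, OC and FM sets.

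Octanal and decanal are straight-chain aldehydes, and the joint fit tested where the responses differ. They were given in different sets, so odor and batch differ together here. Of 923 receptor genes tested, 180 were higher with octanal, 69 with decanal and 44 with both, against 13.5 expected. The expected number takes every receptor gene as equally likely to be called. The responses differed in 182 receptor genes, 144 with octanal above and 38 with decanal above (161 adjusted over the list alone). This was 19.72% of the receptor genes tested, and 29.24% of all genes differed (6032 of 20631). In simulation, changed receptor genes were mostly recovered less often than changed genes of all kinds, so these shares differ in power. Of the 136 higher with octanal only, 109 differed by test, and of the 25 higher with decanal only, 15 did. Of the 44 higher with both, 11 were above with octanal and 7 with decanal. The median difference over the 44 was 0.0013 on the log2 scale, with a median half-width of the 95% interval of 0.96. Octanal was above for Olfr124 by 4.21 (SE 0.358, adjusted p 1.05e-07) and for Olfr398, Olfr1380, Olfr59 and Olfr1243 by 3.07, 5.07, 4.19 and 5.61. Decanal was above for Olfr1426, at -3.39 (SE 0.316, adjusted p 2.84e-07), and for Olfr1254, Olfr129, Olfr55 and Olfr1344 at -3.65, -4.32, -3.07 and -5.43. Olfr332 rose with both odors, by 4.45 with octanal and 5.17 with decanal, and Olfr716 by 5.04 and 4.72. These examples of shared receptors were chosen after values were seen.

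**Figure D4:**
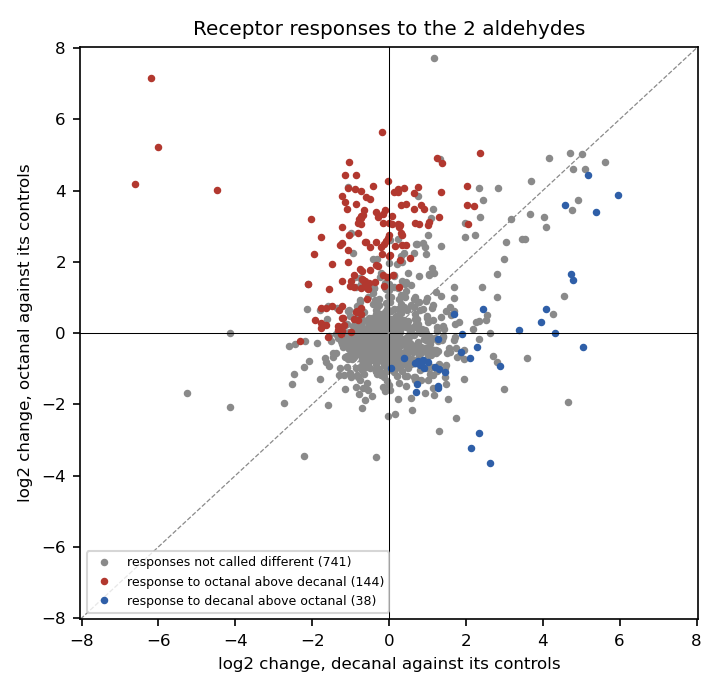
Log2 change against control for 923 olfactory receptor genes with decanal (x axis) and octanal (y axis), each against the controls of its set. Red points mark 144 genes with octanal above by test, blue points 38 with decanal above, and grey points 741 genes not called.

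Similarity between sets was measured over all 27 pairs of odors from different sets, which share no control libraries but differ in batch. In the separate fits of each set, octanal and decanal shared 46 higher receptor genes against 14.1 expected (Fisher's exact test, adjusted p 1.38e-17), with r 0.192 and rho 0.0358 across genes. Decanal and cis-3-hexenol shared 3 against 5.11 (Fisher's exact test, adjusted p 0.487), which, chosen after values were seen, were Olfr716, Olfr1254 and Olfr287. Decanal and mint shared 6 against 7.94 (adjusted p 0.555, Fisher's exact test). Decanal with floral-mint and the AD mixture with cis-3-hexenol also missed the threshold, at adjusted p 0.349 and 0.368. The other 23 pairs passed it, from 31 shared against 22.7 for acetophenone and octanal (adjusted p 0.0493) to the pair of aldehydes. The expected numbers and these tests take every receptor gene as equally likely to be called. A gene that is easier to call in both sets can raise an overlap without a shared response, which was not tested. Across the 9 odor groups 547 receptor genes tested in at least 1 set were higher with none, 82 with 1, 125 with 2 and 2 with 8, which were Olfr110 and Olfr502, chosen after values were seen. The mixtures hold the components of other groups, so these are not counts of distinct odors. A gene not tested in a set could not count there.

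Gene lists were tested in the same 9 comparisons. Olfactory receptors as a list were higher with acetophenone, octanal, cis-3-hexenol, the OC mixture, mint and floral-mint (largest adjusted p 0.00401), with list medians of -0.08 to 0.44 over the 9 comparisons. None of these 6 calls held with an estimated correlation (smallest adjusted p 0.0742). The list median and the test differed in sign for octanal and mint, where the mean was above 0. With scaling to the median receptor gene the list median fell below 0 for acetophenone, cis-3-hexenol, the OC mixture and floral-mint. Class II receptors were higher in 7 comparisons, all but decanal and the AD mixture, with a median below 0 for octanal, floral and mint. Class I receptors were higher with decanal, cis-3-hexenol and the OC mixture and lower with acetophenone, with medians of -0.38 to 0.73. Receptor pseudogenes were higher with decanal, where the median was -0.01, with cis-3-hexenol and with the OC mixture. Their calls and those of class I and class II receptors did not hold with an estimated correlation either (smallest adjusted p 0.0719). The acetophenone responders were higher as a list with acetophenone, the AD mixture and floral-mint, with a median of 4.51 for acetophenone. The floral-mint call, with 2 of the 4 genes called, did not hold (adjusted p 0.321 with an estimated correlation). Trace amine receptors (smallest adjusted p 0.107) and vomeronasal receptors (0.415, tested in 6 comparisons) were not called.

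Genes that neurons raise with activity (10 genes) were higher in all 9 comparisons, with medians of 0.71 to 1.92 and adjusted p of at most 1.64e-05. With an estimated correlation the call held in 3 of the 9, the fragrances, and the largest adjusted p was 0.476. Members called higher numbered 5 to 8 of the 10. Lrrc3b was higher in each, by 1.22 with acetophenone, 1.55 with decanal, 3.43 with octanal and 2.10 with mint, and Pcdh10 by 1.66 to 3.73. Markers of mature sensory neurons (16 genes) were also higher in all 9, with medians of 0.29 to 1.56 and adjusted p of at most 0.00141, and 7 to 16 of the 16 were called. Not 1 of these 9 calls held with an estimated correlation (smallest adjusted p 0.123). Neither list changed direction under any scaling tried. Immediate early genes were higher with octanal, the OC mixture and floral-mint, with medians of 0.02 to 0.54 over the 9 comparisons, but in none of these with an estimated correlation (smallest adjusted p 0.279). With scaling to the median receptor gene the median fell to -0.05 for the OC mixture. Nr4a1, a member, was higher in all 9 by 1.49 to 3.81. Immature sensory neuron markers were not called (smallest adjusted p 0.0524).

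Apart from erythroid genes, markers of other cells were lower where they were called at the preset correlation. With an estimated correlation no list of this paragraph was called (smallest adjusted p 0.0719, for ciliated respiratory markers). Basal progenitor markers were lower in 5 comparisons, with medians of -0.77 to -0.03, namely decanal, the AD mixture and all 3 of the OC set. Sustentacular markers were lower in 6, namely decanal, octanal, the OC mixture and all 3 fragrances, with medians of -0.40 to 0.08. Bowman's gland and ciliated respiratory markers were lower with cis-3-hexenol and the OC mixture, with medians of -1.05 to 0.17 and -0.49 to 0.30. Ensheathing glia markers were lower with acetophenone, octanal, the OC mixture and floral-mint, with medians of -1.06 to -0.10. Immune markers were lower with acetophenone and in all 3 comparisons of the OC set, with medians of -1.35 to 0.18. Microvillar cell markers were not called (smallest adjusted p 0.107). Odorant metabolism genes were lower in 6, namely acetophenone, decanal, the AD and OC mixtures, floral and mint, with medians of -0.47 to -0.08. Interferon genes were lower in all 3 comparisons of the OC set, with medians of -0.64 to 0.48. Electrophile response genes were lower with the AD mixture (adjusted p 0.0448). Heat shock genes were higher with octanal and the OC mixture and lower with decanal, with medians of -0.33 to 0.68. Endoplasmic reticulum stress genes were not called (smallest adjusted p 0.151).

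Lists of abundant RNA also shifted at the preset correlation, though no call of the 3 lists below held with an estimated correlation (smallest adjusted p 0.273 for ribosomal protein, 0.219 for mitochondrial and 0.0742 for erythroid genes). Ribosomal protein genes were higher with decanal, the AD mixture, floral and floral-mint and lower with acetophenone and in all 3 comparisons of the OC set, with medians of -0.83 to 0.69. Mitochondrially encoded genes were lower with octanal and the OC mixture and higher in 6 others, all but acetophenone, with medians of -2.76 to 2.61. Erythroid genes were higher with decanal and floral and lower with acetophenone and in all 3 comparisons of the OC set, with medians of -2.47 to 1.17. Erythroid RNA held 8.19% to 8.81% of counts in OC controls and 0.693% to 2.05% with octanal. It held 1.65% to 2.19% in AD controls and 3.92% to 4.09% with decanal. With acetophenone it held 1.33% in replicate 1 and 0.243% and 0.289% in the others. Mitochondrial RNA held 0.570% to 0.599% in OC controls, 0.0606% to 0.121% with octanal and 0.774% to 2.21% with cis-3-hexenol. Over all 231 list tests the median, mean and test differed in sign in 36, of which 6 were called. With an estimated correlation the calls that held were the acetophenone responders with acetophenone (adjusted p 0.000639) and the AD mixture (0.0140), and the activity list with floral (0.00146), mint (0.00117) and floral-mint (0.00105).

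**Figure D5:**
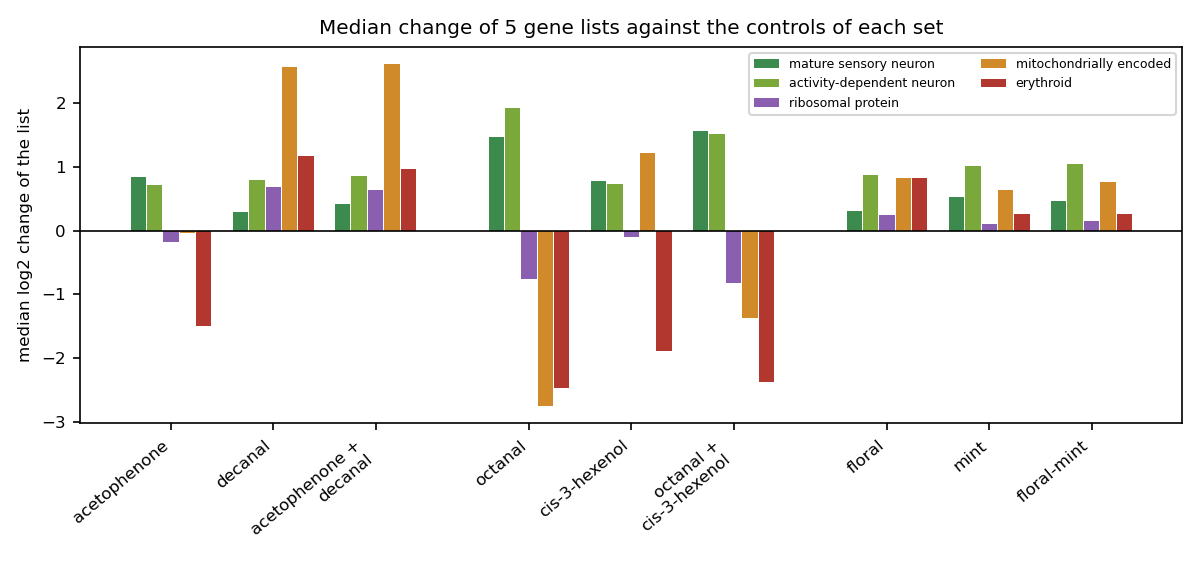
Median log2 change against control (y axis) of mature sensory neuron, activity-dependent, ribosomal protein, mitochondrially encoded and erythroid genes in the 9 comparisons (bars). The neuron and activity lists lie above 0 in all 9 comparisons, and the ribosomal protein, mitochondrial and erythroid lists lie on either side of 0.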

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

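The test of sensory neuron RNA and the scaling to the median receptor gene were chosen after the results were seen, and the test of near-identical copies was written beforehand.

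Receptor genes called against control were higher in 66 and lower in 58 with decanal and higher in 115 and lower in 56 with the AD mixture. For decanal the larger direction turned by DESeq2, with all 36 libraries in a single fit and without a filter on low counts. In the other 7 odor groups the receptor genes called were mostly higher, in 68 to 198 genes, and lower in at most 24. A larger amount of sensory neuron RNA in odor libraries would raise receptor genes together, and mature neuron markers were called higher in all 9 comparisons, though in none with an estimated correlation (smallest adjusted p 0.123). It would then leave a pair of odors of the same set differing in a single direction. Of the 268 receptor genes that differed between acetophenone and decanal, however, the smaller direction held 31.3%, and it held 43.2% in the OC set and 38.3% in the FM set. More neuron RNA as the whole cause is argued against by these values, though it may add to the higher receptor share. Reads shared between near-identical copies are argued against as the main cause too. At most 37.9% of the receptor genes called higher had such a copy in any comparison, and the share was not above that of the other receptor genes by test (Fisher's exact test, adjusted p 0.643 to 0.795). With scaling to the median receptor gene, 59 receptor genes were called higher and 24 lower with cis-3-hexenol, and 165 higher and 58 lower with the OC mixture, the comparisons in which that scaling moved the median of all genes most. A response of particular receptors to particular odors is therefore a hypothesis that these tests leave standing. A shared difference in handling between control and odor mice was not tested.

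The responses to octanal and to decanal differed, by the test of the difference itself, in 182 receptor genes. That is 19.72% of the receptor genes tested. Of all genes 29.24% differed, so genes other than receptors differed as well. These shares differ in power. In simulation for octanal against control, 6.25% of receptor genes and 46% of all genes changed 2-fold were recovered. At a log2 difference of at least 1, 144 of the 923 receptor genes were called with octanal above and 36 with decanal above. Of all 20631 genes, 1501 and 1850 were. Both odors were given in different batches, each with its own controls, so the odor and the batch cannot be told apart for this difference. Of 33 splits of the libraries, the real one included, 1 gave as many receptor genes. Regrouping can mix odor and control, which can widen the spread within groups, so these splits do not exclude chance. The highest of the other splits gave 134. Each odor was regrouped with its own controls separately, so a drawn split can leave 1 odor whole against its controls. Regrouped libraries thus still carried the effects of the odors, and what gave the 134 was not examined. Leaving out octanal replicate 2 gave 179.

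The same test picked out lists of genes with another response to octanal than to decanal. The median log2 difference, octanal minus decanal, was -1.45 for ribosomal protein genes (adjusted p 1.73e-29), -5.41 for mitochondrially encoded genes (5.97e-23) and -3.60 for erythroid genes (2.27e-06). Further lists passed at the preset correlation: immune -1.68, interferon -1.07, mature sensory neuron 1.14, immature sensory neuron 0.43, heat shock 0.94 and class II receptors 0.14. None passed with an estimated correlation, where the smallest adjusted p was 0.136. In the erythroid list all 6 genes tested were lower. The controls of the batches themselves differed, with erythroid RNA at 8.19% to 8.81% of counts in the OC set and 1.65% to 2.19% in the AD set. Mitochondrial RNA held 0.570% to 0.599% in OC controls and 0.0505% to 0.0673% in AD controls. The tissue was perfused, a step that removes blood. No explanation was tested, and odor and batch are confounded here as well.

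Some receptor pseudogenes, which the comparisons of receptor genes did not use, were called higher than control. As a list they were called higher with decanal, cis-3-hexenol and the OC mixture, in none of the 9 comparisons with an estimated correlation (smallest adjusted p 0.0719), and their median was -0.30 with the AD mixture. The numbers called higher were 3 with acetophenone, 5 with decanal, 7 with the AD mixture, 10 with octanal, 5 with cis-3-hexenol, 10 with the OC mixture, 3 with floral, 2 with mint and 2 with floral-mint. The numbers called lower were 3 with decanal, 3 with the AD mixture, 4 with octanal and 1 with the OC mixture, and edgeR called no pseudogene lower in the other 5. The genes in the groups of 5 or fewer were named after their values were seen. With acetophenone they were Olfr1025-ps1, Olfr105-ps and Olfr896-ps1, higher by 4.28, 5.61 and 2.21. With decanal they were Olfr718-ps1, Olfr764-ps1, Olfr766-ps1, Olfr1326-ps1 and Olfr1372-ps1, by 6.28, 5.95, 5.53, 2.68 and 1.76. With cis-3-hexenol they were Olfr1274-ps, Olfr1224-ps1, Olfr175-ps1, Olfr766-ps1 and Olfr1174-ps, by 2.93, 2.32, 2.67, 4.13 and 3.02. With floral they were Olfr1192-ps1, Olfr175-ps1 and Olfr1369-ps1, by 2.40, 1.60 and 0.89. With mint they were Olfr1192-ps1 and Olfr237-ps1, by 3.29 and 3.79, and with floral-mint Olfr1192-ps1 and Olfr175-ps1, by 3.03 and 0.97. Several have a near-identical copy with which they can share reads, which was not tested: Olfr1192-ps1 with Olfr475-ps1 (98.3% identity), Olfr1174-ps with Olfr1175-ps (95.8%), Olfr1372-ps1 with Olfr1383 (96.3%), Olfr764-ps1 with Olfr766-ps1 (95.4%), Olfr1274-ps with Olfr1506 (96.4%), Olfr1369-ps1 with Olfr263 (97.9%) and Olfr237-ps1 with Olfr441 (95.1%). Olfr718-ps1, for which no such copy was found, was higher by 5.29, 3.21 and 3.17 with the AD mixture, octanal and the OC mixture as well. No explanation was tested for the pseudogenes.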

How the results depend on the processing

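Scaling to the median receptor gene, removal of the genes of 4 lists, and the closer look at leaving out octanal replicate 2 and acetophenone replicate 1 were chosen after seeing the data. With scaling to the median receptor gene, the larger direction over all genes turned from higher to lower for acetophenone, octanal, the OC mixture and floral-mint and from lower to higher for decanal, and some list medians fell below 0, as given below. Where genes called higher and lower were close in number, the larger direction turned in other alternatives too: over all genes for decanal, the AD mixture and cis-3-hexenol, and over receptor genes for decanal and for floral-mint against mint. Receptor genes with decanal were 73 higher and 74 lower by DESeq2, 79 and 80 with all 36 libraries in a single fit, and 66 and 74 without a filter on low counts. With relative log expression size factors, TMM without receptor genes or removal of the 4 lists, every count computed was within 1.5 times its value in the report. Of 3762 alternative values for the named genes, 3631 kept direction and side of the threshold, 131 fell short of the threshold in the same direction (98 of them with 1 library left out) and 0 reversed. Most of these genes were named for the smallest p in the same libraries. That choice favors values that hold, so these numbers do not measure how stable the calls of other genes are. The calls lost most often were Olfr536 in the FM interaction and Olfr789 in the AD interaction, in 11 alternatives each. Unless stated, the cause of a change was not tested.

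Adjusted over the list alone, where fewer genes are tested, receptor counts were 110 for the AD mixture against decanal, 22 for the OC mixture against octanal, 25 for the OC interaction, and 30 and 58 for floral-mint against floral and against mint. The other 14 counts were within 1.5 times. Without a filter on low counts they were 89 for the AD mixture against decanal, 28, 59 and 91 for the AD, OC and FM interactions, 128 for cis-3-hexenol, 41 for the OC mixture against octanal, and 45 and 78 for floral-mint against floral and against mint. Over all genes cis-3-hexenol then gave 1993.

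DESeq2 gave 1924 genes for acetophenone and 1997 for cis-3-hexenol, and receptor counts of 87 for the AD mixture against decanal (67 higher and 20 lower), 17 for the OC mixture against octanal, 45 for floral-mint against mint, and 27 and 33 for the AD and OC interactions. With only the 6 libraries of the groups compared, a fit with fewer samples, the counts were 585 for acetophenone, 2180 for cis-3-hexenol and 1324 for mint over all genes, and 7 receptor genes for the OC mixture against octanal.

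With all 36 libraries in a single fit, cis-3-hexenol gave 103 receptor genes and 3182 genes in all (1824 higher and 1358 lower). Floral gave 60 receptor genes (59 higher and 1 lower) and 781 genes (643 and 138), mint 76 receptor genes and 682 genes (563 and 119), and floral-mint 653 genes (523 and 130). The acetophenone count, 1325, stayed within 1.5 times but split into 851 higher and 474 lower, and the 12 receptor genes of floral-mint against mint into 10 and 2. The OC and FM interactions gave 28 and 25.

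The replicate numbers of the labels do not pair the libraries of different groups. With the replicate number as a block the AD interaction gave 0 receptor genes, and the other 27 counts stayed within 1.5 times.

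Scaling to the median receptor gene moved the median of all genes by more than 0.1, to -0.14 for acetophenone, -0.20 for octanal, -0.46 for cis-3-hexenol and -0.50 for the OC mixture. The counts over all genes were 291 for acetophenone (145 higher and 146 lower), 2210 for decanal, 1896 for the AD mixture (1195 and 701), 4681 for cis-3-hexenol (103 and 4578), 1332 for floral, 1101 for mint and 965 for floral-mint (408 and 557). Octanal stayed within 1.5 times in number at 5024, but its split became 1703 higher and 3321 lower. For the OC mixture, 7653 genes split into 909 and 6744. Among the lists called, the median of olfactory receptors then fell from 0.0138 to -0.135 with acetophenone, from 0.444 to -0.029 with cis-3-hexenol, from 0.243 to -0.188 with the OC mixture and from 0.0355 to -0.052 with floral-mint, and that of immediate early genes from 0.429 to -0.0547 with the OC mixture. This scaling is set by the receptor genes and moves all genes of a library alike, so it cannot tell whether receptors as a class rose, and these falls are no change of a list against other genes.

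With an estimated correlation the gene lists called numbered 1, 0 and 1 for acetophenone, decanal and the AD mixture, 0, 0 and 0 for octanal, cis-3-hexenol and the OC mixture, and 1, 1 and 1 for floral, mint and floral-mint.

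Leaving out each library in turn, counts over all genes ran from 386 to 1175 for acetophenone, 2879 to 3846 for decanal, 2695 to 3452 for the AD mixture, 3932 to 7044 for octanal, 271 to 566 for cis-3-hexenol, 967 to 2046 for floral, 982 to 3336 for mint and 839 to 1743 for floral-mint. The lowest values came without acetophenone replicate 2, decanal replicate 1, AD control replicate 2, octanal replicate 1, cis-3-hexenol replicate 2, and FM control replicate 1 for the last 3. Without mint replicate 3 the mint count was 3336. Receptor counts ran from 45 to 57 for cis-3-hexenol (45 without its replicate 1), 7 to 13 for the OC mixture against octanal (7 without octanal replicate 2 or mixture replicate 1) and 83 to 126 for the OC mixture against cis-3-hexenol (83 without cis-3-hexenol replicate 2). The AD interaction ran from 0 to 7 (0 without control replicate 3 or decanal replicate 2), the OC interaction from 4 to 24 (24 without octanal replicate 2) and the FM interaction from 30 to 66 (30 without floral-mint replicate 3). Leaving out acetophenone replicate 1 gave 1091 genes and 108 receptor genes for acetophenone. On simulated data with these depths, spreads and group sizes, 6.25% to 28.3% of receptor genes changed 2-fold were recovered, and depth was not varied.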

Other observations

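The tests of a shared composition shift in the AD and OC sets, of scale noise in each set and of the sum of log changes as the reference were chosen after the results were seen, and the test of shared controls was written beforehand.

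Over genes other than receptors, mixture libraries lay at the place of a single component, near decanal in the AD set and near octanal in the OC set. Over all receptor genes tested the positions were 0.0111 ± 0.0445 in the AD set, 0.199 ± 0.0345 in the OC set and 0.0387 ± 0.0106 in the FM set, and -0.0191 ± 0.0346 and 0.163 ± 0.0367 in the AD and OC sets over those that differed between the components. Noise of the libraries that define the scale is argued against as the cause of the OC position, since with any component library left out of the scale it stayed on the side of octanal, at 0.136 ± 0.0308 or more. It stays open for the small offsets of the other mixtures, which crossed the middle, to -0.0229 without acetophenone replicate 3 and to -0.0054 without floral replicate 2. A test of this noise written beforehand, that left-out component libraries lie on their own side of the middle, was met by all 18 (nearest 0.224, octanal replicate 3), but it was replaced because it does not bear on where the mixture lies. A shift in RNA composition may be shared by the mixture and a component, for instance in ribosomal, mitochondrial or erythroid RNA. It predicts that receptor genes alone, centred as described above, place the mixture midway, within 0.1 of the middle. The AD mixture was at most 0.0301 from the middle with any component library left out, so such a shift is a candidate explanation for the likeness of decanal and mixture libraries outside the receptors. The OC mixture lay beyond 0.1 by more than 2 SD with all libraries but not without octanal replicate 3 (0.136), so a composition shift and a receptor profile nearer octanal cannot be told apart for it without relying on that library. A biological dominance of octanal and the amount of each odorant (the components of a mixture shared the volume that a single odorant filled) stay open and untested.

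The floral-mint fragrance lay below the sum of the log2 changes of its components for 47 receptor genes. Over all genes it did so for 496, so the shortfall was not confined to receptors. At a log2 departure of -1 or lower there were 131 genes, and 45 of them were receptor genes. Receptor genes were 847 of the 19204 tested. Chance values of the controls enter every term of the sum. Over 20 simulated tables of unchanged groups, the highest number of receptor genes below the sum was 0. Tables without any change yield few calls, so this 0 cannot decide whether control values contributed, and that stays open. The sum of log2 changes may itself be too high a reference. If a receptor already raised by a fragrance does not rise further with another, the mixture would lie near the higher component. Over the 47 receptor genes higher with both fragrances, floral-mint minus the higher component had a median of -0.181, with quartiles of -0.309 and -0.0911, and floral-mint lay below both components in 17.0%. Responses that level off would give such values, but addition of another form is not excluded. A sum of log2 changes multiplies the folds, and a sum of the folds themselves was not tested. For the 39 receptor genes higher with both components of the OC mixture the median was -0.0721, with quartiles of -0.316 and 0.0985, and the mixture lay below both components in none. For the 5 of the AD mixture the median was -0.588, and it lay below both in 2. The reading of a levelling off was found and tested on the same data. It does not separate a limit in the neurons from a limit of the pS6 assay. The amount of each fragrance in floral-mint was not varied and stays open as well.

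Other splits of the samples were tried for every count. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. For receptor genes against control the real values were 118, 124, 171, 208, 68, 205, 97, 121 and 113 for acetophenone, decanal, the AD mixture, octanal, cis-3-hexenol, the OC mixture, floral, mint and floral-mint, and the highest other split gave 0 in each. Over all genes the real values were 1071, 4354, 4168, 6321, 1123, 6357, 2698, 2145 and 1851, and the highest other split gave 1 for cis-3-hexenol and mint and 0 for the rest. For mixtures against components the real values were 156 and 53 in the AD set, 11 and 131 in the OC set and 18 and 18 in the FM set, and the highest other split gave 1 for the OC mixture against octanal and for floral-mint against mint, and 0 for the rest.

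For the interactions 33 splits of the 12 libraries were drawn, the real one included. In the FM set 1 of the 33 gave as many receptor genes as the real value of 49, and the highest other gave 0. In the AD set 1 of the 33 gave as many as the real value of 7, and the highest other gave 1. The drawn groups mixed libraries of different odors, which can widen the spread within groups and lower the calls. These splits therefore do not exclude chance in either set. The AD call is also fragile, at 0 with the replicate number as a block. The count was 4, 1 and 0 without control replicates 1, 2 and 3, 3 without acetophenone replicate 2, 3, 0 and 1 without decanal replicates 1, 2 and 3, and 4, 2 and 4 without mixture replicates 1, 2 and 3. In the OC set 2 of the 33 gave as many as the real value of 7, and chance cannot be excluded. The highest other split gave 54. The regrouped libraries still carried the effects of the odors, which can give calls in a drawn split, and what gave the 54 went untested. The real count was 24 without octanal replicate 2, 18 without octanal replicate 3, and 4 without control replicate 1 or 3, octanal replicate 1, or mixture replicate 1 or 2.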
